A study of Homo sapiens with 36 samples.

How the data were processed

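Messenger RNA was measured in human monocyte-derived dendritic cells from 18 patients, in 36 libraries that form 18 pairs. Each pair held a double-loaded culture, given amplified tumour mRNA together with tumour lysate, and an mRNA-loaded control culture of the same patient's cells. The labels put 7 pairs in batch 1, 6 pairs in batch 2 and 5 pairs in batch 3, with both members of a pair in the same batch. RNA was extracted with Trizol, poly(A) RNA was captured on oligo-dT beads, and the libraries were sequenced with paired-end reads on an Illumina NovaSeq instrument, per the labels.

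The authors deposited, for each batch, a table of counts per gene and a table of FPKM values per gene. The deposited counts are whole numbers that follow from trimming with fastp, alignment with HISAT2 2.0.5 and counting with featureCounts 1.5.0-p3 on GRCh38 (hg38), per the submitters' processing notes. The fastp version, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited FPKM values divide the counts by gene length and by an effective library size that was 0.754 to 1.216 times the library's total, as recomputed from the count table of the same batch, so the authors had applied a scaling factor to them. Gene symbols, positions and biotypes were those of the deposited tables.

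The 3 count tables were joined on gene identifier, which gave 58735 genes, and all 72 per-library columns of counts and FPKM were matched to a label, with 0 unmatched. Total counts per library ran from 12895166 to 29345614 in the mRNA-loaded group (median 19564991) and from 10058141 to 26740685 in the double-loaded group (median 20425856). No library was identical to another (0 identical library pairs). Y-linked genes (518) and 16 other genes whose level can reflect a donor's sex or genotype were left out for privacy before any fit, which left 58201 genes.

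Genes were kept with edgeR's filterByExpr on the loading group (minimum count 10, minimum total count 15), which left 14787 genes, of which 12333 are protein-coding. Libraries were scaled by TMM. The loading effect was tested with edgeR 4.0.16 (quasi-likelihood F test, robust, 17 residual degrees of freedom) with the patient pair as a block, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. The pair block also takes up the batch. A difference of the loading effect between the 3 batches was tested with 2 numerator degrees of freedom in 1 fit of batch-specific loading terms. All tests are two-sided. Standard errors of the log2 fold changes were derived from the fold change and its F value, and intervals are 95% intervals. CPM values are scaled by TMM, and log2 CPM used a prior count of 2.

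A set of 34 gene lists, covering immune functions, metabolism, library quality and marker transcripts of other cell types, was tested with limma 3.58.1 (camera, preset inter-gene correlation 0.01, at least 3 tested members), and beside it with a correlation estimated per list and with fry. The agreement of the pairs was described by the mean correlation across genes of the within-pair log2 differences, with 100 random sign flips of the pairs as a reference. Differences of library measures and of list means within pairs used permutation tests with 100000 sign flips, and correlations across patients used 100000 permutations.

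The lists, the panel of 16 genes, the tests and the rule for naming genes were chosen before the data were examined. The rule named, where fewer than 5 genes passed, the 10 protein-coding genes with the lowest p, the member with the lowest p of each list, and every tested gene of the panel, which made 57 genes, of which 1 is not given in the text. Other genes in the text were chosen after their values were seen. The alternatives chosen at the same time were scaling by RLE size factors and by upper quartile, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM in 18 libraries), log2 FPKM with 1 or 0.1 added, a 2-fold minimum, no pair block, each batch alone, and leaving out each pair in turn. Weights per pair in limma-voom and the omission of the 2 pairs with the widest within-pair change were added later.

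The fits were checked on simulated counts for 14787 genes in 18 pairs. With 50 genes changed at each size, 16 were recovered at 1.25-fold, 37 at 1.5-fold, 47 at 2-fold and 50 at 4-fold, with 8 false calls. Unchanged simulated data gave 0 calls by edgeR, with 665 genes at an unadjusted p under 0.05. When the deposited counts of 200 genes were thinned to impose a known change, 25.5% were recovered at 1.25-fold, 74.5% at 1.5-fold, 94.5% at 2-fold and 100% at 4-fold. A simulated 2-fold difference between batches was recovered for 99 of 200 genes. In these checks the changed genes were drawn only from genes above a minimum mean CPM. Recovery for genes of lower expression was not measured. Of the named genes, 21 overlap a tested gene on the opposite strand, and without a known strand setting their reads cannot be told apart from that gene's. The software was R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.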

Results

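Poly(A) RNA was counted in 36 libraries of monocyte-derived dendritic cells, 18 from cultures loaded with amplified tumour mRNA and 18 from cultures of the same patients loaded with that mRNA and tumour lysate. Dendritic cells present antigen to T cells, and double loading offers epitopes of the same tumour to the MHC class I and class II routes at once. The libraries held between 10058141 and 29345614 counts each. The chemokines CCL22 and CCL17 were among the abundant transcripts of the mRNA-loaded cells, at 28790 ± 20980 CPM and 10360 ± 7711 CPM (SD, n = 18). The maturation genes FSCN1 (4738 ± 3019 CPM) and LAMP3 (1148 ± 396 CPM) were also well covered, and the monocyte gene CD14 stood at 2400 ± 1760 CPM.

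Patients differed far more than loadings. Expression deviations from the batch and loading mean correlated at a mean r of 0.642 across genes within a pair (0.327 to 0.853) and at −0.12 between different pairs of a batch, where centring on the batch mean alone gives a value below 0, and 36 of the 36 libraries were closest to the other library of their own pair. At the median gene, 73.6% of the variance lay between patients of a batch, 4.79% between batches, 0.61% between loadings and 17.9% in the remainder. The interferon-stimulated gene ISG15 ranged from 50.7 to 15130 CPM among the mRNA-loaded libraries, and IFIT1 from 3.66 to 1129 CPM.

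The comparison of double-loaded with mRNA-loaded cells asks whether adding lysate changed the transcriptional state of the vaccine cells. Lysate brings protein for endocytosis and class II presentation, and a change could have appeared in costimulatory genes such as CD80, CD86 and CD40, in the T cell polarizing cytokine genes IL12A and IL12B, or in regulatory genes such as CTLA4, CD274 and IDO1. Lysate of brain tumour also contains heme, lipid and debris of glial cells, to which HMOX1 and GFAP relate. Both cultures were given tumour mRNA, so GFAP counts cannot tell debris in the lysate from loaded mRNA.

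Between the loadings 0 of 14787 genes passed the threshold by edgeR (lowest adjusted p = 0.966), with 600 genes at an unadjusted p under 0.05 (216 higher and 384 lower in double-loaded cells) where independent null genes would give 739. Labels swapped at random within pairs gave as many in 14 of 60 splits, with a median of 312 and a highest count of 2145. In each count of such splits the real labelling is 1 of the 60, while medians and highest counts are over the others. DESeq2 also gave 0 genes (408 higher and 422 lower at an unadjusted p under 0.05), as did limma-voom (504 higher and 370 lower). The count depended on the low-count filter: with all 39113 genes that had a count, edgeR called 38 genes, 3 higher and 35 lower, each of which was also tested with the filter. PDGFRL, SHISA3, JMJD8, HMGCS1 and DDIT4 were among them. Labels swapped at random within pairs gave as many without the filter in 5 of 60 splits, with a median of 2 and a highest count of 202.

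The 95% interval of the fold change had a median half-width of 0.195 on the log2 scale for the 8456 genes at 10 CPM or more, and 99.7% of these genes had an interval within 2-fold in either direction. For the 4951 genes at 1 to 10 CPM the half-width was 0.505, with 80.8% of intervals within 2-fold. Below 1 CPM it was 0.948 for 1380 genes, with 17.2% within 2-fold.

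The protein-coding genes with the lowest p, none of which passed the threshold, moved in 13 to 16 of 18 pairs. PDGFRL (chr8:17576433-17644071, GRCh38), a gene related to the PDGF receptor, measured 20.5 ± 11.7 CPM in mRNA-loaded and 15.7 ± 10.7 CPM in double-loaded cells, a log2 fold change of −0.51 (SE 0.12, p = 0.000382), and was lower in 16 of 18 pairs. The cytokine receptor gene IL20RB (chr3:136946230-137011085) measured 6.21 ± 7.32 and 9.03 ± 10.5 CPM, a log2 change of 0.48 (SE 0.13, p = 0.00087), and was higher in 15 pairs. SHISA3 (chr4:42397839-42402487), which encodes an adaptor that restrains WNT and FGF signalling, measured 4.85 ± 6.3 and 2.57 ± 3.37 CPM and had the largest fitted change of these genes, a log2 value of −1.17 (SE 0.33, p = 0.00188), with 15 pairs lower and 0 higher. The remaining pairs were tied, and the lowest mRNA-loaded library held 0 CPM of SHISA3, so this gene lies near the floor.

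VKORC1 measured 16.3 CPM and 21.4 CPM (log2 0.37, p = 0.00196; higher in 16 pairs), and the respiratory complex I gene NDUFA3 59.8 and 82.3 CPM (log2 0.32, p = 0.00287; higher in 13 pairs). The translation factor gene EEF2 measured 774.9 and 660.8 CPM (log2 −0.21, p = 0.00249; lower in 16 pairs). SPOP had a log2 change of −0.23, EPDR1 of −0.41 and JMJD8 of −0.72, with 15, 13 and 16 pairs lower. PDGFRL, EPDR1, NDUFA3 and JMJD8 overlap MTUS1, SFRP4, TFPT and STUB1 on the opposite strand, so their counts may include reads of those genes. Across all tested genes, 40 moved in the same direction in 16 or more pairs, where independent genes would give 19 by chance. Labels swapped within pairs gave as many in 6 of 60 splits, with a highest count of 243.

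The 95% intervals of the costimulatory and maturation genes of the panel all included 0. CD86 measured 730.3 ± 233.9 CPM in mRNA-loaded and 702 ± 241 CPM in double-loaded cells, a log2 change of −0.06 (95% interval −0.21 to 0.08). CD40 changed by a log2 value of −0.12 (−0.28 to 0.04), CD83 by −0.19 (−0.51 to 0.12) and CD80 by −0.18 (−0.64 to 0.28). For CD86, CD40, CD83 and CD80 these intervals exclude a 2-fold change in either direction. The lymph node homing receptor gene CCR7 was abundant, at 2528 ± 935 and 2371 ± 1247 CPM, and its interval was wide (log2 −0.30, −1.01 to 0.41), with 10 pairs higher and 8 lower. These fitted values depended on 1 or 2 pairs: with each pair left out in turn the log2 change ran from −0.34 to −0.13 for CCR7, −0.23 to −0.06 for CD83, −0.23 to −0.02 for CD80, −0.08 to −0.02 for CD86 and −0.16 to −0.07 for CD40, and without the 2 pairs with the widest within-pair change it was −0.01 for CCR7 and −0.04 for CD80.

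The cytokine gene IL12B, which encodes the p40 chain of IL-12 and IL-23, was low and varied between patients, at 8.38 ± 20.6 and 5.34 ± 13.9 CPM, and its log2 change was −0.48 (−1.55 to 0.60, p = 0.364). IL12A had a count in 19 libraries, with a maximum of 33 counts, and was removed by the low-count filter. IL23A had a log2 change of −0.05, IL6 of −0.19, IL10 of −0.15 and TNF of 0.17. Among regulatory genes, CTLA4 measured 4.10 and 3.76 CPM (log2 −0.40, −1.29 to 0.48), CD274 771.9 and 718.9 CPM (log2 −0.19, −0.48 to 0.11) and IDO1 1547 and 1426 CPM (log2 −0.32, −1.03 to 0.39). With each pair left out in turn the log2 change ran from −0.58 to −0.19 for CTLA4, −0.22 to −0.06 for CD274, −0.36 to −0.14 for IDO1 and −0.62 to −0.15 for IL12B. It ran from −0.32 to −0.02 for IL6 and 0.07 to 0.29 for TNF, and its sign changed for IL23A (−0.12 to 0.11) and GFAP (−0.03 to 0.32). HMOX1, which answers to heme, measured 264.8 and 265.5 CPM (log2 −0.03, −0.16 to 0.11; −0.06 to −0.01 with each pair left out). The glial gene GFAP was near the detection limit in both groups, at 0.826 ± 0.859 and 1.03 ± 1.13 CPM (log2 0.14, −0.89 to 1.17).

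**Figure D1:**
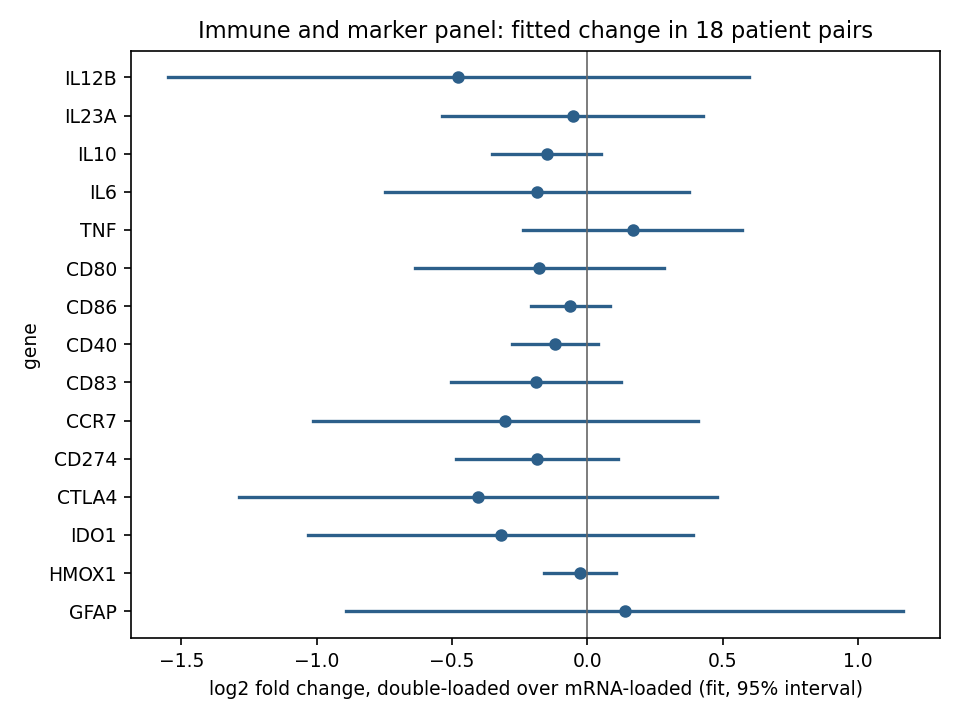
Fitted log2 fold change of double-loaded over mRNA-loaded cells in 18 pairs (points) with its 95% interval (lines), for the 15 tested genes of the panel. The intervals of all 15 genes cross 0, and none of them passed the threshold after adjustment over 14787 genes.

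The gene lists ask whether small changes shared by genes of 1 function add up. Interferon-stimulated genes, MHC class I genes, NF-kB targets and costimulatory genes are switched on as dendritic cells mature, and ribosomal protein genes and the nuclear genes of oxidative phosphorylation report the cells' translational and metabolic state. With a preset correlation, camera put 6 of 34 lists past the threshold, 4 lower and 2 higher in double-loaded cells, and 0 with an estimated correlation (lowest adjusted p = 0.955; 1 list at an unadjusted p under 0.05). By fry 0 lists passed (lowest adjusted p = 0.492; 2 at an unadjusted p under 0.05). Of the 598 tested members, 0 passed over all genes and 0 adjusted over the list alone, by edgeR.

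Interferon-stimulated genes fell by the preset test (38 members, 36 fitted lower; adjusted p = 8.02e-07, and adjusted p = 0.955 with an estimated correlation). Their mean log2 difference within pairs was −0.23 ± 0.59 (SD, n = 18), with 13 of 18 pairs lower. IFIT1, the member with the lowest p, measured 245.4 ± 287.8 and 224.3 ± 268.9 CPM (log2 −0.34, p = 0.0127), and ISG15 had a log2 change of −0.09. The IFIT1 locus overlaps LIPA on the opposite strand.

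MHC class I presentation genes fell by the preset test (20 members, 17 lower; adjusted p = 0.00397, and adjusted p = 0.955 with an estimated correlation), by a mean of −0.10 ± 0.22 with 13 pairs lower. Their member TAPBPL had a log2 change of −0.16 (p = 0.0121), and B2M, named after its value was seen, measured 12240 ± 2032 and 10890 ± 2219 CPM (log2 −0.18, p = 0.0252; lower in 16 pairs). Costimulation and maturation genes fell by the preset test (20 members, 19 lower; adjusted p = 0.00397, and adjusted p = 0.955 with an estimated correlation) with a mean of −0.30 ± 1.07 and 11 pairs lower. ICAM1 had a log2 change of −0.32 (p = 0.116; −0.17 without 1 pair). NF-kB inflammatory genes fell by the preset test (26 members, 23 lower; adjusted p = 0.00397, and adjusted p = 0.955 with an estimated correlation), with a mean of −0.23 ± 1.00, 12 pairs lower, and a log2 change of −0.30 for SOD2 (p = 0.0414; −0.18 without 1 pair).

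Ribosomal protein genes rose by the preset test (48 members, 44 higher; adjusted p = 7.39e-05, and adjusted p = 0.955 with an estimated correlation). Their mean within pairs was 0.07 ± 0.43, yet only 8 of 18 pairs were higher and the median pair stood at −0.03, so mean and median differ in sign. RPS28, whose counts may include reads of pseudogenes and of genes on the opposite strand, had a log2 change of 0.24 (p = 0.0246). Oxidative phosphorylation genes rose by the preset test (35 members, 27 higher; adjusted p = 0.00397, and adjusted p = 0.955 with an estimated correlation), with a mean of 0.08 ± 0.39 and 10 pairs higher. NDUFA13 had a log2 change of 0.48 (p = 0.0167).

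The list means were far from 0 in 2 pairs, those with the widest within-pair change. In these pairs costimulation and maturation genes differed by −4.46 and −1.06, NF-kB genes by −4.08 and 0.96, interferon-stimulated genes by −2.33 and −0.79, and ribosomal protein genes by −0.59 and 1.38 on the log2 scale. Within each list the lower value is given first, so the order does not follow the pairs. Without these 2 pairs camera with a preset correlation put 0 lists past the threshold and 6 at an unadjusted p under 0.05. Of those 6, only ribosomal protein genes (p = 0.00679) were among the lists called with all pairs. The means without these 2 pairs were 0.00 for costimulation, −0.06 for NF-kB, −0.06 for interferon-stimulated, −0.03 for MHC class I, 0.03 for ribosomal protein and 0.03 for oxidative phosphorylation genes. Permutation of the signs of the 18 list means gave p = 0.0673 for interferon-stimulated genes, 0.0455 for MHC class I, 0.27 for costimulation, 0.481 for NF-kB, 0.524 for ribosomal protein and 0.499 for oxidative phosphorylation genes, all between 0.457 and 0.743 after adjustment over the lists.

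**Figure D2:**
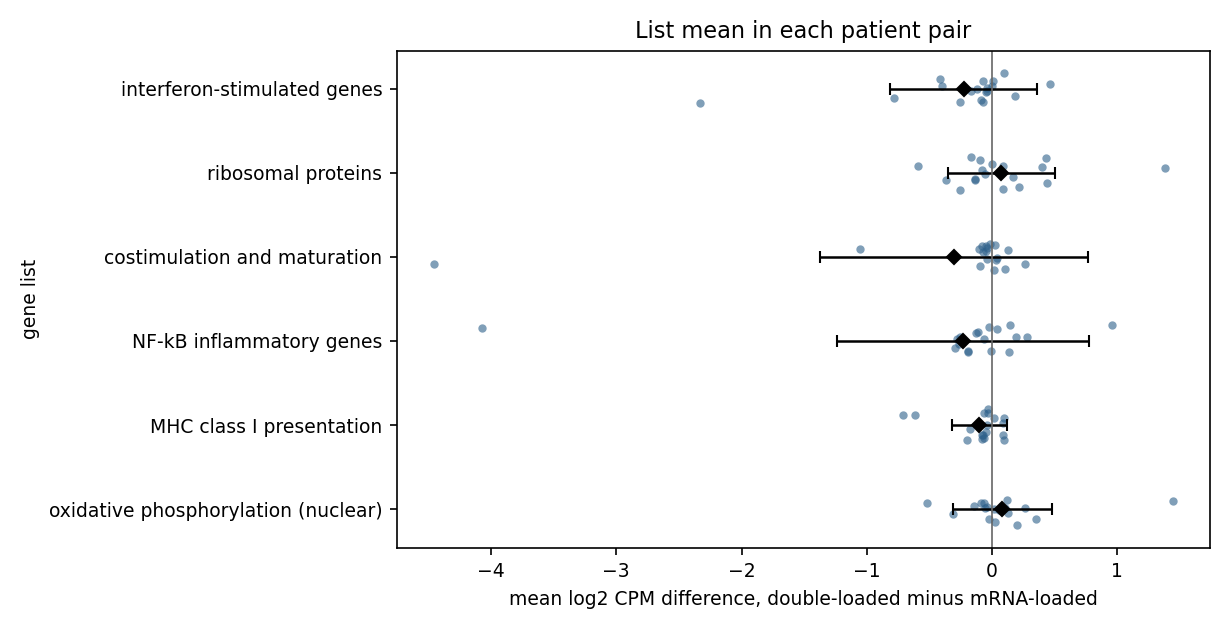
Mean log2 CPM difference of each list between the double-loaded and the mRNA-loaded library of a pair (points, 18 pairs per list), with the mean and SD over pairs (diamonds and bars), for the 6 lists past the threshold with a preset correlation. Points below −2 occur for interferon-stimulated genes (−2.33), costimulation and maturation genes (−4.46) and NF-kB genes (−4.08), while most pairs lie near 0.

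The other 28 lists did not pass. Astrocyte and glioma transcripts came closest (13 members tested, 10 lower, adjusted p = 0.0533 by camera with a preset correlation), with CHI3L1 at a log2 change of −0.17. They were the 1 list at an unadjusted p under 0.05 with an estimated correlation (p = 0.0496, adjusted p = 0.955). By fry they (p = 0.0159) and proliferation genes (p = 0.0318) were the 2 such lists, with an adjusted p of 0.492 each. Without the 2 widest pairs the astrocyte and glioma list had camera p = 0.0423 with the preset correlation (adjusted p = 0.24) and 0.117 with an estimated one. The loaded tumour mRNA, given to both groups, may also hold astrocyte and glioma transcripts. Lysosome and autophagy genes and proliferation genes had an adjusted p of 0.0937 each, immediate early genes 0.099, mitochondrially encoded mRNAs 0.14, and metallothionein and zinc genes 0.22 (camera, preset correlation). T cell polarizing (Th1) cytokine genes stood at 0.571, tolerogenic and checkpoint genes at 0.56, glycolysis genes at 0.571, unfolded protein response genes at 0.627, and NRF2 targets and erythroid markers at 0.668. Cholesterol synthesis genes, hypoxia targets and endothelial, pericyte and fibroblast markers had 0.951 each. The adjusted p was 0.967 for heme and iron handling, endocytic and C-type lectin receptors, MHC class II presentation, PPAR and fatty acid genes, LXR and cholesterol efflux, heat shock genes and histone mRNAs. Neutrophil, platelet, monocyte and macrophage, T and NK cell, B and plasma cell markers and neuron and oligodendrocyte transcripts also stood at 0.967.

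Members with the lowest p of these lists did not pass the threshold in edgeR. DDIT4, a stress and hypoxia gene, measured 77.3 ± 36.4 and 66.4 ± 45.4 CPM (log2 −0.39, p = 0.00454; lower in 14 pairs). SQSTM1, which encodes the autophagy receptor p62, had a log2 change of −0.31 (p = 0.012), IER5 of −0.29 (p = 0.0111) and AHR of −0.18 (p = 0.0151). The sterol synthesis gene HMGCS1 had −0.41 (p = 0.0191), the scavenger receptor gene CD163 −0.31 (p = 0.0353), the zinc exporter gene SLC30A1 −0.20 (p = 0.0251) and EDEM1 −0.25 (p = 0.0429). The other 18 ranged from a log2 change of −0.74 for BANK1 to 0.21 for OSGIN1, with an unadjusted p above 0.05. Among them, log2 changes were −0.16 for LGMN, −0.19 for TNFSF9, −0.27 for MCM6, −0.43 for GP1BA, −0.42 for HBD, −0.67 for COL1A1, −0.24 for IL7R and −0.23 for PFKM. They were −0.16 for PLTP, −0.19 for HILPDA, −0.09 for DNAJA1, −0.15 for HIST1H2AC, −0.13 for MMP9, −0.14 for CNP and 0.18 for MT-ND3. Leaving out 1 pair brought TNFSF9 to −0.05, HILPDA to −0.13, EDEM1 to −0.15, HIST1H2AC to −0.05, IL7R to −0.10, GP1BA to −0.28, HBD to −0.19 and MMP9 to −0.07.

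Whether the effect of lysate differed between the 3 batches was asked because patients were processed in batches of 7, 6 and 5 pairs. By edgeR 0 genes differed (lowest adjusted p = 0.993), with 319 at an unadjusted p under 0.05, and limma-voom also gave 0, with 451. PDGFRL had a log2 change of −0.50, −0.27 and −0.83 in batches 1, 2 and 3, and IL20RB of 0.31, 0.59 and 0.58, in the fit with batch-specific loading terms. In the same fit SHISA3 had −1.002 in batch 1, −1.07 in batch 2 and −1.75 in batch 3. Of the panel, CTLA4 had 0.78, −0.97 and −1.61 (edgeR test between batches, p = 0.0483, adjusted p = 0.993). In the same order IL6 had −0.79, −0.10 and 0.49, IL12B −1.15, 0.29 and −0.80, and TNF −0.14, 0.20 and 0.53. Signs also differed between batches for IL23A, IL10, CD80, CD86 and GFAP. They were the same for CD40, CD83, CCR7, CD274, IDO1 and HMOX1. Ribosomal protein genes had a mean difference of 0.32 in batch 1, −0.09 in batch 2 and −0.08 in batch 3, and the difference between batches was not past the threshold (permutation p = 0.13, adjusted p = 0.983 over the lists).

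Agreement between patients in their response was the last comparison, since a shared response to lysate would move the pairs together. The within-pair log2 differences of 2 patients correlated at a mean of 0.00596 across genes (−0.221 to 0.247), and 12 of 100 random sign flips of the pairs gave a mean as large, with a maximum of 0.0326. Genes are not independent replicates, so this value describes these libraries. The SD of the within-pair differences ran from 0.14 to 1.44 among pairs, with a median of 0.34.

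Of 7 library measures, the share of counts in protein-coding genes differed, at 97.2% ± 0.40 in mRNA-loaded and 97.0% ± 0.42 in double-loaded cells (mean difference −0.142 percentage points, lower in 14 of 18 pairs, permutation p = 0.0179, not adjusted over the measures). The mitochondrial share was 4.35% ± 1.54 and 4.36% ± 1.37 (permutation p = 0.97), and the ribosomal protein share 2.89% ± 1.03 and 3.12% ± 1.36 (permutation p = 0.238).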

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

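Weights per pair and the omission of the 2 widest pairs were chosen after the results were seen, and the other alternatives were planned. The count of genes past the threshold was 0 in each direction under RLE and upper quartile scaling, DESeq2, limma-voom, the stricter filter, both FPKM pseudocounts, a 2-fold minimum and each batch alone. It was also 0 in each of the 18 fits that left out a pair (0 to 0 in each direction, 388 to 938 genes at an unadjusted p under 0.05, lowest adjusted p 0.124). Without the filter edgeR called 3 genes higher and 35 lower (275 and 1086 at an unadjusted p under 0.05), and the cause was not tested. The 38 genes had a median total of 38253 counts. With weights per pair limma-voom called 4 higher and 2 lower; 2 of these 6 passed without the pair of highest weight, and 4 with library size as a covariate. Of the genes given in the text, PDGFRL, SHISA3, JMJD8, HMGCS1 and DDIT4 passed without a filter (adjusted p 0.0144, 0.00849, 0.0386, 0.0122 and 0.0166), and SHISA3 and IL20RB with weights. RLE scaling gave 284 genes higher and 275 lower at an unadjusted p under 0.05, against 216 and 384 with TMM, so that imbalance depended on scaling.

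Leaving out the pair block gave 0 genes higher and 0 lower (42 and 7 at an unadjusted p under 0.05), 0 genes differing between batches (23 at an unadjusted p under 0.05) and 4 lists. The count of genes whose loading effect differed between batches was 0 under each alternative run, and 0 to 0 with each pair left out.

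The count of lists moved from 6 to 0 with an estimated correlation, because camera then takes up the correlation of the members, which reached 0.823 for ribosomal protein genes. It was 0 with fry, which asks another question. It was 4 in batch 1 alone. Batch 2 alone, with fewer pairs, gave 1 list, ribosomal protein genes in the opposite direction. Batch 3 alone, also with fewer pairs, gave 1 list that is not among the 6. This was mitochondrially encoded mRNAs, which were higher (adjusted p = 0.0293, camera with the preset correlation, an estimated one not being run there). So none of the 6 passed in its called direction in batch 2 or batch 3 alone. Without the 2 widest pairs the count was 0, and 0 also with an estimated correlation. With weights per pair it was 4: interferon-stimulated genes (adjusted p = 0.00769) and NF-kB genes (0.0448) passed, as did glycolysis genes (0.0252) and monocyte and macrophage markers (0.0369), all lower, with the preset correlation. Without weights the latter lists stood at 0.571 and 0.967, and all 4 at 0.955 to 0.98 with an estimated correlation, which was not run with weights. It ranged from 1 to 8 with each pair left out: omitting 1 pair left 1 list, the interferon-stimulated genes, which passed in 18 of the 18 fits. RLE scaling and the stricter filter gave 7. Ribosomal protein genes reversed in batch 2 alone, where they were lower (adjusted p = 8.89e-05 with the preset correlation, no estimated one being run there), and the cause was not tested; the difference between batches had permutation p = 0.13.

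The mean correlation of the pair differences, 0.00596, was 0.0155 with genes at 10 CPM or more, and the cause was not tested, 0.00735 with a prior count of 5 and 0.0129 without the 2 widest pairs. Of 1815 alternative values of the 57 named genes, 29 changed sign, none of them past the threshold. Intervals were widest for genes below 1 CPM, of which 17.2% had an interval within 2-fold.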

Other observations

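The test of the 2 widest pairs was chosen after the list results were seen, as were the weights per pair and the relation of interferon-stimulated to ribosomal protein genes. Splits that swap the loading labels at random within pairs were used to ask whether chance can be excluded. The splits include the real labelling. For a count of 0 genes they say nothing, since any split gives as many: 60 of 60 did for the loadings and 40 of 40 for the batches, with a highest other of 0 in each. For the 38 genes without a filter chance cannot be excluded, since 5 of 60 splits gave as many (dispersion trend held at that of the real labels). The highest other gave 202, several times the real count, and the source of such a high count was not tested.

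The 6 lists past the threshold with a preset correlation could not be set apart from chance: 35 of 60 splits gave as many lists, and the highest other gave 12. The 2 pairs with the widest within-pair change are a candidate source of these calls, since 0 lists passed without them. With weights per pair, which lower the influence of variable pairs, interferon-stimulated and NF-kB genes passed with the preset correlation, for which label swaps and an estimated correlation were not run (adjusted p = 0.955 for both without weights), so this decides nothing on those pairs. A shift shared by most patients stays open for interferon-stimulated and MHC class I genes, with 13 of 18 pairs lower each (sign test p = 0.0963 each). That count does not set them apart, since lists that did not pass had as many. Proliferation and cholesterol synthesis genes were lower in 13 of 18 pairs, and hypoxia targets in 14. For ribosomal protein genes 8 of 18 pairs were on the called side, a minority. Why the 2 pairs with the widest within-pair change differ also stays open, and no biological explanation of it was tested.

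With weights per pair limma-voom called 6 genes, SHISA3 (log2 −0.88, adjusted p = 0.000499), IL20RB (0.65, adjusted p = 0.00291), LAD1 (0.56), ZBTB32 (0.63) and TNNT2 (0.64, adjusted p = 0.0146 for these 3), and SPP1 (−0.43, adjusted p = 0.0325), while edgeR without weights gave 0.24 for LAD1 (p = 0.504; −0.03 in batch 1 alone), 0.34 for ZBTB32 (p = 0.19), 0.25 for TNNT2 (p = 0.474) and −0.25 for SPP1 (p = 0.186), whose mean CPM ran the other way, from 482.7 to 942.1. The annotated loci of LAD1 (chr1:201373244-201399915) and TNNT2 (chr1:201359008-201377762) overlap, so these may not be independent calls. Chance cannot be excluded, since 4 of 60 splits gave 6 or more genes. The highest other gave 952, and the source of such a high count was not tested. Without the pair of highest weight 2 of the 6, SHISA3 and IL20RB, passed, while LAD1 (0.52), ZBTB32 (0.69), TNNT2 (0.57) and SPP1 (−0.45) had similar fold changes with an adjusted p of 0.0538 to 0.135, so that pair may be a source of their precision more than of their size. Library size within pairs as the whole cause was argued against, since 4 of the 6 passed with log2 library size as a covariate. An effect of lysate on SHISA3, lower in 15 of 18 pairs and tied in the rest, and on IL20RB, higher in 15 of 18 pairs, stays open as a hypothesis. SHISA3 lies near the floor, with 0 CPM in the lowest mRNA-loaded library.

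Across the 18 mRNA-loaded libraries the mean level of interferon-stimulated genes ran against that of ribosomal protein genes (r = −0.625, permutation p = 0.0061, adjusted p = 0.0231; rho = −0.612, permutation p = 0.00793, adjusted p = 0.0262; 33 relations tested), with r = −0.785 in batch 1 (n = 7, exact p = 0.0552), −0.512 in batch 2 (n = 6, exact p = 0.251), too few samples in batch 3, and r = −0.72 in the double-loaded libraries of the same patients. Depth and batch were argued against as the whole cause, since r was −0.637 after both were removed (permutation p = 0.00514). Gene length bias was argued against in the same way (r = −0.788 after its slope was removed, permutation p = 0.00012), although that slope itself followed ribosomal protein genes (r = −0.785). The relation did not rest on the 2 patients farthest from the median, as r was −0.635 without them (permutation p = 0.00976). The interferon list also ran with histone mRNAs (r = 0.817), neuron and oligodendrocyte transcripts (r = 0.777), metallothionein genes (r = 0.681), NF-kB genes (r = 0.672), T and NK cell markers (r = 0.579) and MHC class I genes (r = 0.561, but 0.373 without the 2 patients and rho adjusted p = 0.0827), and against PPAR and fatty acid (r = −0.671), oxidative phosphorylation (r = −0.641), mitochondrially encoded (r = −0.629), cholesterol synthesis (r = −0.611) and MHC class II genes (r = −0.607). Only 5 of 25 listed histone mRNAs and 4 of 20 listed neuron and oligodendrocyte transcripts were tested. Their means rest on few genes. The lists related to the interferon list cover immune and lipid functions as well as library quality and markers of other cell types. Tested members of these marker lists include abundant transcripts, such as CNP (272.8 CPM in mRNA-loaded cells) and IL7R (358.9 CPM). The counts do not tell which cells these transcripts came from, so the relations are not evidence of other cells. No source of the relation was singled out, and no biological explanation was tested because the design names none for differences between patients.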
